A study of Mus musculus with 12 samples.

How the data were processed

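The data were microarray measurements of microglia, the resident macrophages of the brain, from mice with an intact Lrrc33 gene (Lrrc33+/+, called WT) and mice labelled Lrrc33-/- (called KO-labelled). Lrrc33 is the older symbol of Nrros, whose protein anchors latent TGF-beta1 on myeloid cells. Per the labels' protocols, brain cells of mice aged 3 weeks were sorted by flow cytometry as CD45low, CD11b+, CD39+ and Ter119- cells, total RNA was isolated with Trizol, and biotin-labelled samples were hybridised to Affymetrix mouse exon arrays with 1 channel. Each group held 3 samples that the labels call biological replicates. The labels do not say how many mice went into a sample, and p-values measure only the spread between these samples.

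The same 6 samples appear at a gene level, with 1 value per transcript cluster, and at an exon level, with 1 value per probeset, which gives 12 labelled columns in all. The deposited values of both levels are on the log2 scale. The authors summarised them with RMA, per the submitters' processing notes, a method that corrects background, normalizes arrays to a common distribution and summarises probes. For the exon level the same notes also name oligo and limma, with no role or version. RMA pulls low signals towards a common floor, which makes fold changes of dim genes too small. The version of RMA, the array annotation and the genome build are not given in the sources used here, so no probe positions were used. Gene positions, for the test of genes within 10 Mb of Nrros, came from a RefSeq gene table. The gene-level table held 16755 transcript clusters and 1236087 probesets stood at the exon level. Every value column was mapped to a labelled sample, and 0 columns were left unmapped.

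The series states 6 samples, so the exon-level columns were taken as a second summary of the same arrays and never as independent evidence. This was checked on deviations from group means over 14048 genes. Each gene-level column correlated with its own exon-level column at r = 0.463 to 0.554 and with any other column at no more than 0.0379, across genes, which are not independent replicates. Array medians lay between 6.70 and 6.76 (log2) at the gene level and between 5.82 and 5.84 at the exon level. The number of arrays limits the precision.

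Gene names came from the platform annotation, updated by gene identifier and symbol through a RefSeq gene table of assembly GRCm38.p6, which was used for names, for which genes neighbour each other and for gene positions in the test around Nrros. At the gene level 14996 clusters had 1 gene symbol, all matched to that table, 1019 had several and 740 had none. At the exon level 321091 probesets had 1 symbol, of which 320193 matched and 898 kept the symbol as given, 7796 had several and 907200 had none. No gene was named from a feature with several symbols. A gene with several clusters was represented by the cluster with the highest mean over the 6 arrays.

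Differences are KO-labelled minus WT. They were tested with limma (version 3.58.1 in R 4.3.3, lmFit and eBayes, no trend, not robust, two-sided, no covariate) over all features of a table, with Benjamini-Hochberg adjustment and a threshold of 0.05. Errors of differences are moderated standard errors, and SD is given over n = 3 samples. Differential exon usage was tested with limma's diffSplice (F test per gene) on probesets with 1 symbol whose higher group mean was at or above the median of all probesets, in genes with at least 3 such probesets. This left 236961 probesets in 16692 genes. Gene lists were tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists with at least 5 measured members. Of 26 lists, 24 were tested and 2 were too small.

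The following choices were made before the data were examined: the tests, the lists, most alternatives and the rule for named genes. The lists covered homeostatic microglia, TGF-beta pathway components, TGF-beta target genes, border-associated macrophages, disease-associated microglia, MHC class II and class I presentation, interferon response, inflammatory cytokines and NF-kB, cell cycle, lysosome and phagocytosis, cholesterol and lipid metabolism, immediate early and stress genes, glycolysis and hypoxia, and oxidative phosphorylation. Lists for other cell types, whether near the gate or carried along despite it, covered monocytes, neutrophils, lymphocytes and NK cells, dendritic cells, neurons, astrocytes, the oligodendrocyte lineage, endothelial and mural cells and erythroid cells. Chromosomal neighbours of Nrros and sex-linked genes completed the set. Some genes stand in more than 1 list. The rule named Nrros and the sort markers Ptprc, Itgam and Entpd1. It also named the 12 genes with the largest rise and the 12 with the largest fall among clusters with 1 symbol, past the threshold and with no overlap between groups. From each list it took up to 4 members past the threshold with the largest fold change, or up to 2 where none passed, and for exon usage the 3 genes with the smallest p. Other genes named were chosen after their values were seen, and are said to be so.

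The procedures were tested on simulated data made from the means and variances of the arrays. At the gene level, with 200 of 16755 clusters changed, limma recovered 64.2% of those shifted by 0.5 (log2), 92.5% of those shifted by 1 and 97.0% of those shifted by 2, and 4.52% of its calls were false. With 200 of 1236087 probesets changed, 0 were recovered at the exon level. With 20000 probesets changed by each of these sizes, limma recovered 5.49% at 0.5, 52.7% at 1 and 89.1% at 2, with 5.06% false calls. Camera called all 5 lists shifted by 0.5 and 0 of the 19 others, with genes simulated as independent. diffSplice called 55.0% of genes with 1 probeset shifted by 1 and 99.0% with 1 shifted by 2. It also called 1.90% of genes shifted as a whole and 198 of 16492 genes without a single shifted probeset (1.20%). These were 56.2% of its 352 calls, so its adjusted p was far too small in this simulation.

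Alternatives covered a replicate block, leaving out each sample, a second quantile normalization, median centring, eBayes with trend and robust settings, removal of the dimmest features, array weights, 1 cluster per gene, gene values rebuilt from exon-level probesets, an equal-variance test per gene, a 2-fold minimum, removal of sex-linked genes, and male signal as a covariate. List tests were repeated with an estimated correlation, with fry and without shared genes. Exon usage was repeated with other probeset filters and the Simes test. Alternatives chosen after seeing the data were the counts of list members with each sample left out, exon usage among genes with little gene-level change, and the fits of single genes, lists and Nrros probesets under the settings above. Families of genes examined after the data were seen are described as such.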

Results

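Gene expression was measured in microglia sorted from the brains of mice aged 3 weeks, in 3 WT samples and 3 KO-labelled samples (labelled Lrrc33-/-). The comparison asks how microglial RNA differs when Nrros, formerly Lrrc33, is lacking. Cells were sorted as CD45low, CD11b+, CD39+ and Ter119-, and RNA was read on Affymetrix mouse exon arrays with 1 array per sample, summarised by the authors with RMA on the log2 scale. The number of arrays limits the precision. The arrays covered 16755 transcript clusters at the gene level and 1236087 probesets at the exon level. Between samples of the same group, gene-level values correlated at r = 0.9938 to 0.9956 across clusters, and between groups at 0.9592 to 0.9655. The first principal component separated the groups and held 82.9% of the variance.

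Nrros, the targeted gene, was not lower in the KO-labelled samples. Its transcript cluster (6845154) had a mean of 9.81 ± 0.18 (log2, SD, n = 3) in WT and 9.86 ± 0.03 (SD, n = 3) in KO-labelled samples. The difference of 0.05 (SE 0.09) did not pass limma's test (Benjamini-Hochberg adjusted p = 0.759), and it was -0.053 without WT replicate 3. At the exon level 8 probesets carry the symbol Nrros, and their differences ran from -0.25 to 0.42 with a median of 0.14. That median was 0.063 without WT replicate 3, 0.082 without KO replicate 1 and 0.234 without WT replicate 2. None of the 8 passed limma's test, with a lowest Benjamini-Hochberg adjusted p of 0.31, and 0 had an unadjusted p under 0.05. The mean of every Nrros probeset stayed above the median of all probesets (5.82) in the KO-labelled samples, where the dimmest had a mean of 6.68. limma's diffSplice found no differential exon usage in Nrros (Benjamini-Hochberg adjusted p = 0.258). The structure of the allele and the positions of these probesets are not given in the sources used here, and a probe outside a deleted part checks nothing. The arrays therefore do not bear out the genotype labels by RNA, and all directions reported here rest on those labels.

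**Figure D1:**
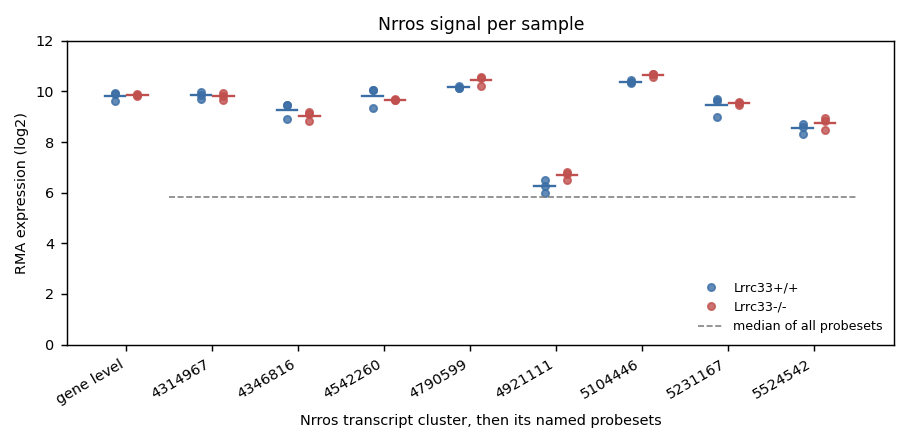
RMA expression of Nrros (log2, vertical axis) in each sample, at the gene level and for the 8 probesets named Nrros. Points are samples, short lines are group means, and the dashed line is the median of all exon-level probesets (5.82). The gene-level group means are 9.81 and 9.86.

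RNA of the surface markers used for the sort differed between the groups. Itgam, which encodes CD11b, fell by 1.81 (log2, SE 0.07), to a level 3.51-fold lower in KO-labelled samples (limma, Benjamini-Hochberg adjusted p = 5.5e-06). Ptprc, which encodes CD45, was 1.37-fold higher, with a log2 change of 0.46 (SE 0.07; limma, Benjamini-Hochberg adjusted p = 0.0031). Entpd1, which encodes CD39, fell by 0.36 (SE 0.07; limma, Benjamini-Hochberg adjusted p = 0.0079), but missed the threshold after a second quantile normalization (-0.24, adjusted p = 0.072). WT replicate 3 differed from the other 5 samples in sex-linked RNA. The median over its probesets of Xist, named after its values were seen, was 7.96 (log2), against 12.2 to 12.5 elsewhere, and its Y-linked Eif2s3y reached 7.89, against 2.75 to 3.09. With 1 such sample in WT and 0 in the KO-labelled group, Eif2s3y (-1.54, SE 1.16) and Kdm5d (-0.91, SE 0.72) differed by less than the spread between replicates (limma, Benjamini-Hochberg adjusted p = 0.404 and 0.426). Without that sample their differences were -0.00041 and 0.040.

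Genes characteristic of microglia were among those that fell most in the KO-labelled samples, while genes of other macrophage types were among those that rose most. In all, 4758 of 16755 transcript clusters passed limma's test (28.4%), of which 2420 were higher and 2338 lower. A change of at least 2-fold was seen in 482 higher and 374 lower clusters. Without WT replicate 3, 4159 clusters passed.

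The largest fall was that of Sall1 (6984093), a zinc finger transcription factor of microglial identity. It went from 11.28 ± 0.06 (log2, SD, n = 3) in WT to 5.50 ± 0.05 in KO-labelled samples, a 55.2-fold difference (log2 change -5.79, SE 0.06; limma, Benjamini-Hochberg adjusted p = 3e-08). Adgrg1, an adhesion G protein-coupled receptor, fell by 4.91, and Sparc, a matricellular glycoprotein, by 4.84. Tjp1, a scaffold of tight junctions, fell by 4.92 and St3gal5, which makes the ganglioside GM3, by 4.88. The fructose transporter gene Slc2a5 fell by 4.72 and the adenosine receptor gene Adora3 changed by -4.63, but by -1.06 with gene values from exon-level probesets. Rasgrp3, an activator of Ras proteins, changed by -4.47, the small GTPase gene Gem by -3.75, and Gp9, a subunit of the platelet von Willebrand factor receptor, by -3.64. With gene values from exon-level probesets Gp9 changed by -1.90. The protease gene Adamts1 changed by -3.60 and the microglial membrane protein gene Tmem119 by -3.55. Standard errors of these 12 changes ran from 0.05 to 0.25, and the highest adjusted p was 5e-05 (limma, Benjamini-Hochberg).

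The largest rise was that of Mmp13 (6986719), a collagenase, from 4.96 ± 0.10 (log2, SD, n = 3) to 10.07 ± 0.21, a 34.5-fold difference (log2 change 5.11, SE 0.11; limma, Benjamini-Hochberg adjusted p = 4.3e-07). Spic, a transcription factor of red pulp macrophages of the spleen, rose by 4.80. Rnase2a, of the eosinophil-associated ribonucleases, rose by 4.57. Cd4, known as a T cell co-receptor, rose by 4.32 and the adhesion molecule gene Vcam1 by 4.21. Clec4n, which encodes the fungal receptor dectin-2, rose by 4.21 and Mgl2, a galactose-binding lectin, by 3.81. Ch25h, which makes an oxysterol, was higher by 3.85 and Cd55, an inhibitor of complement, by 3.84. The proton-sensing receptor gene Gpr65 and the interferon-inducible gene Ifi203 were each higher by 3.73, and Vav3, which encodes a signalling protein of immune cells, by 3.67. Standard errors of these 12 changes ran from 0.05 to 0.37, and the highest adjusted p was 0.00027 (limma, Benjamini-Hochberg).

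**Figure D2:**
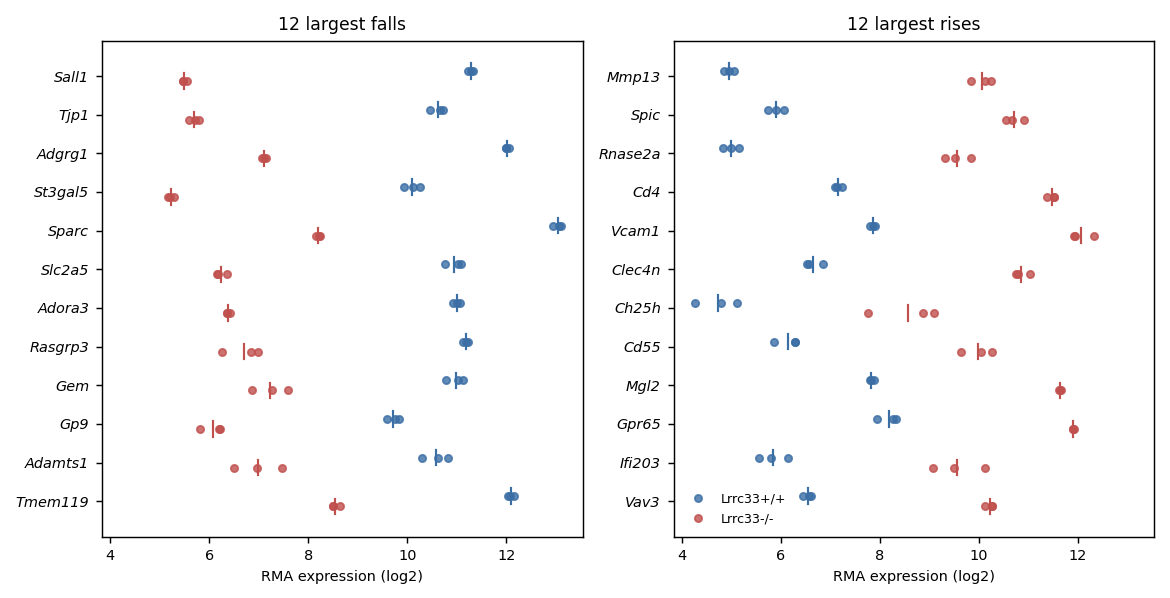
RMA expression (log2, horizontal axes) of the 12 genes with the largest falls and the 12 with the largest rises among genes past limma's threshold with no overlap between groups. Points are samples, 3 per group, and vertical ticks are group means. Sall1 went from 11.28 to 5.50 and Mmp13 from 4.96 to 10.07, and the groups do not overlap for any gene shown.

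Of 30 measured genes of homeostatic microglia, 29 fell in the KO-labelled samples and 0 rose. Besides Sall1, Adgrg1, Sparc and Slc2a5, the falls ran down to 0.24 for Csf1r, the receptor for the growth factor CSF1, and the complement gene C1qa stood at 0.01, both named after their values were seen. The median change was -1.35 (log2; camera, Benjamini-Hochberg adjusted p = 6e-23). With an estimated correlation within lists the adjusted p was 0.021. Of 21 measured genes of border-associated macrophages, which line the vessels and membranes of the brain, 19 rose and 0 fell, or 20 that rose when adjusted over the list alone. Clec4n and Mgl2 led, followed by the chemokine gene Pf4 (3.22, SE 0.08) and the sialic acid receptor gene Siglec1 (2.65, SE 0.17). Lyve1, the hyaluronan receptor that marks part of these cells, named after its values were seen, did not pass (0.12). The median change was 2.05 (camera, Benjamini-Hochberg adjusted p = 7e-20, and adjusted p = 0.047 with an estimated correlation). Leaving out any sample kept the counts at 29 lower for the homeostatic list and at 19 to 20 higher for the border-associated list.

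Interferon-responsive genes rose in the KO-labelled samples, with 16 of 19 higher and 0 lower. The antiviral enzyme gene Oas2 rose by 3.24 (SE 0.28), its relative Oasl2 by 1.93 (SE 0.32), Mx1 by 1.80 (SE 0.37) and Ifit1 by 1.78 (SE 0.37). KO replicate 3 had the highest mean of the list, 9.35 (log2), against 8.60 and 8.49 in the other KO-labelled samples and 7.53 to 7.70 in WT. Without KO replicate 3, 16 members were higher and 1 was lower, and the median change went from 1.36 to 0.96. The higher count was 13 without WT replicate 1 or 2 and 15 without KO replicate 1. Without WT replicate 3 it was 14, and 1 member was lower too. Mx1 and Ifit1 missed the threshold in the equal-variance test (adjusted p = 0.073 and 0.076), and Ifit1 rose by 1.16 with gene values from exon-level probesets. Cell cycle genes rose too, with 19 of 20 higher and 0 lower. The proliferation marker Mki67 rose by 2.45 (SE 0.12), the topoisomerase gene Top2a by 2.31 (SE 0.11), the kinetochore motor gene Cenpe by 1.96 (SE 0.09) and the cyclin gene Ccna2 by 1.92 (SE 0.10). Camera called both lists with Benjamini-Hochberg adjusted p = 2.3e-06 for interferon response and 1e-15 for cell cycle. Both calls were lost with an estimated correlation, where the adjusted p was 0.555 and 0.208.

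The 21 measured TGF-beta pathway components split into 3 that were higher, 7 that were lower and 11 that did not pass, with 1 higher without WT replicate 2. The integrin subunit gene Itgb3 fell by 2.23 (SE 0.05), the coreceptor gene Eng by 1.82 (SE 0.12), the signal transducer gene Smad3 by 1.28 (SE 0.08) and the receptor gene Tgfbr1 by 1.27 (SE 0.06). Of 20 measured TGF-beta target genes, 2 were higher and 9 lower, with 12 past the threshold when adjusted over the list alone. Smad7, a feedback inhibitor of the pathway, fell by 2.60 (SE 0.13) and Ldlrad4, another inhibitor, by 1.72 (SE 0.09). Against these, the matricellular gene Ccn1 rose by 3.61 (SE 0.10) and Tgfbi, a secreted adhesion protein gene, by 1.77 (SE 0.07). Camera called both lists lower (Benjamini-Hochberg adjusted p = 0.034 for components and 0.020 for targets), and neither call held with an estimated correlation (adjusted p = 0.619 and 0.555). The call of the components was also lost without WT replicate 2 (adjusted p = 0.093) and without KO replicate 2 (adjusted p = 0.052), with gene values from exon-level probesets (adjusted p = 0.069) and without genes held by several lists (adjusted p = 0.080). The median of the components was -0.075, and it was -0.119, -0.039 and -0.043 without WT replicate 1, WT replicate 2 and KO replicate 3, and -0.157 without the dimmest clusters. The call of the targets was lost without the dimmest clusters (adjusted p = 0.0501), where their median went from -0.28 to -0.18.

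Of 15 measured genes of glycolysis and hypoxia, 8 were lower and 1 higher. The higher gene, Pfkp (0.30), named after its values were seen, missed the threshold without WT replicate 1 or 3 or any KO-labelled sample. The regulatory enzyme gene Pfkfb3 fell by 1.72 (SE 0.11), the hexokinase gene Hk2 by 1.27 (SE 0.06), the glucose transporter gene Slc2a1 by 1.13 (SE 0.08) and the lactate transporter gene Slc16a3 by 0.95 (SE 0.08). Camera called this list lower (Benjamini-Hochberg adjusted p = 0.0017), a call lost with an estimated correlation (adjusted p = 0.208). With gene values from exon-level probesets 8 of its 20 members were lower and 0 higher. Of the 5 members added there, enzymes of glycolysis, 1 was lower. Oxidative phosphorylation was not called by camera (Benjamini-Hochberg adjusted p = 0.106), with 4 of 14 members higher and 1 lower. The higher count was 2 without WT replicate 1 or with the replicate block. Cox5a was higher by 0.55, Ndufb8 by 0.47 and Sdhc by 0.26, and Uqcrc2 changed by -0.23. Sdhc missed limma's threshold without WT replicate 1 or 2 (Benjamini-Hochberg adjusted p = 0.063 and 0.066). Uqcrc2 missed it without any 1 sample except KO replicate 3 (highest adjusted p 0.070). With gene values from exon-level probesets Cox5a, Ndufb8, Sdhc and Uqcrc2 all missed it (adjusted p = 0.120, 0.080, 0.074 and 0.114), with Cox5a at 0.27, and 1 of 20 members was higher. In fry's directional test, which asks whether members move on balance 1 way and does not compare them with other genes, this list passed as higher (adjusted p = 0.0026).

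Disease-associated, lysosomal, lipid, inflammatory and stress genes moved in both directions within each list, and camera called none of these 5 lists. Fry's directional test, against no change, passed 3 of them, disease-associated microglia, lysosome and phagocytosis, and cholesterol and lipid metabolism (adjusted p = 0.013, 0.00065 and 0.023). In disease-associated microglia, 9 of 21 genes were higher and 4 lower (camera, Benjamini-Hochberg adjusted p = 0.079). Ch25h, the receptor tyrosine kinase gene Axl (3.47, SE 0.16) and the growth factor gene Igf1 (2.45, SE 0.07) rose, while Csf1 fell by 2.80 (SE 0.35). Among lysosome and phagocytosis genes, 10 of 23 were higher and 7 lower, and 20 passed when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.079). The scavenger receptor genes Msr1 (3.54, SE 0.09) and Cd36 (1.94, SE 0.20), Axl and the protease gene Ctsc (1.39, SE 0.06) rose. Among cholesterol and lipid genes, 7 of 21 were higher and 5 lower, and 14 passed when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.361). The nuclear receptor gene Pparg (1.58), the lipid droplet gene Plin2 (1.55) and the cholesterol exporter gene Abcg1 (1.35) rose, and Insig1, a regulator of sterol synthesis, fell by 1.67.

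Inflammatory genes were divided as well, with 8 of 25 higher and 10 lower, and 19 past the threshold when adjusted over the list alone (camera, Benjamini-Hochberg adjusted p = 0.681). The cytokine gene Il10 rose by 2.66 (SE 0.17), while Il1a fell by 2.55 (SE 0.22), Tnf by 2.13 (SE 0.31) and Socs3, a feedback inhibitor of cytokine signalling, by 2.48 (SE 0.15). Among immediate early and stress genes, 6 of 22 were higher and 7 lower (camera, Benjamini-Hochberg adjusted p = 0.681). The chaperone gene Dnajb1 (1.05) and Nr4a2 (0.94) were higher, while Egr2 was lower (-0.97) and Junb fell to 49.9% of its WT level. Dnajb1 missed the threshold in the equal-variance test (adjusted p = 0.065). Of 5 measured genes of MHC class II presentation, Cd74 rose by 0.95 and H2-Oa fell by 2.77, and 3 passed when adjusted over the list alone. Without WT replicate 2 or KO replicate 1 the higher count was 2. The median of this list was 0.18, its mean -0.22 and camera's direction upward (Benjamini-Hochberg adjusted p = 0.545). That median was 0.35 without KO replicate 1 and 0.11 without KO replicate 3, and 0.090 and 0.105 with array weights and with gene values from exon-level probesets. Of 8 genes of MHC class I presentation, the peptide transporter gene Tap1 (0.73) and the immunoproteasome gene Psmb9 (0.43) were higher (camera, Benjamini-Hochberg adjusted p = 0.176, and 0.033 with gene values from exon-level probesets). Psmb9 missed limma's threshold without WT replicate 1, 2 or 3 (Benjamini-Hochberg adjusted p = 0.057 to 0.071), and in the equal-variance test (adjusted p = 0.096).

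Markers of monocytes, neutrophils, astrocytes and vessel cells did not rise as groups. Of 10 monocyte genes 0 were higher and 4 lower, namely Plac8 (-0.98), the chemokine receptor gene Ccr2 (-0.83), Hp (-0.63) and Vcan (-0.28). With gene values from exon-level probesets Ccr2 changed by -0.41, and Vcan did not pass (-0.15, adjusted p = 0.431). The count of 4 was 1 without WT replicate 2 or KO replicate 1, and 2 without WT replicate 3 or KO replicate 2. Of 14 neutrophil genes only Csf3r, the receptor for a granulocyte growth factor, passed (-1.20, SE 0.09), against 3 genes without KO replicate 3. The neutrophil list varied between arrays within groups, with sample means of 7.25, 8.23 and 7.63 (log2) in WT replicates 1 to 3 and 7.01, 6.50 and 7.56 in the KO-labelled ones. Of 9 astrocyte genes the glutamate transporter gene Slc1a3 (-1.50) and Clu (-0.71) were lower, and 1 passed when adjusted over the list alone. Without WT replicate 1, 5 astrocyte genes were lower, and without any other 1 sample 1 was. Of 13 endothelial and mural genes Pecam1 (-1.43), Kdr (-0.75) and Vtn (-0.53) were lower, and 5 genes were without WT replicate 3. Camera called these 4 lists lower, each with Benjamini-Hochberg adjusted p = 0.034, and all 4 calls were lost with an estimated correlation (adjusted p = 0.472, 0.679, 0.625 and 0.655). They were also lost without WT replicate 2 (highest adjusted p 0.234) and without KO replicate 2 (highest adjusted p 0.171). The monocyte, neutrophil and endothelial calls were lost without KO replicate 1 (highest adjusted p 0.067), and the astrocyte call without KO replicate 3 (adjusted p = 0.064) or with array weights (adjusted p = 0.053). Without the dimmest clusters all 4 were lost (adjusted p = 0.279, 0.0746, 0.0756 and 0.0960). The monocyte call was lost with gene values from exon-level probesets (adjusted p = 0.090). In fry's directional test, which sets a list against no change and not against other genes, the monocyte and astrocyte lists passed (adjusted p = 0.010 and 0.048) and the neutrophil and endothelial lists did not (adjusted p = 0.143 and 0.085). Without WT replicate 2 the medians of the neutrophil, astrocyte and endothelial lists went from -0.61, -0.37 and -0.26 to -0.34, -0.21 and -0.11. The neutrophil median was -0.39 without KO replicate 2, and the astrocyte median -0.58 without WT replicate 1.

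Of 14 lymphocyte and NK cell genes only Cd4 passed, while the T cell receptor complex genes Cd3e (0.21) and Cd3g (0.11), named after their values were seen, did not. Without KO replicate 2, 2 lymphocyte genes passed. Camera's adjusted p for this list was 0.079 (Benjamini-Hochberg), with 0.043 and 0.044 without KO replicates 1 and 2, 0.296 without KO replicate 3 and 0.101 without WT replicate 1. Its median of 0.11 was 0.019 and 0.056 in these last 2 cases. In fry's directional test, against no change, the list passed as higher (adjusted p = 0.0026). Of 9 dendritic cell genes Zbtb46 (0.27) was higher, and Cd209a (-0.69) and Btla (-0.23) lower (camera, Benjamini-Hochberg adjusted p = 0.545). Their WT means of 6.49, 6.50 and 5.55 (log2) lay below the array medians. Of 12 neuronal genes 0 passed limma's test, and 2 had an unadjusted p under 0.05, Snap25 (0.42, Benjamini-Hochberg adjusted p = 0.064) and Rbfox3 (0.13, adjusted p = 0.109). Snap25 passed with the replicate block and without the dimmest clusters (adjusted p = 0.037 and 0.039), and Rbfox3 in the equal-variance test (adjusted p = 0.047). Of 13 oligodendrocyte genes Mobp (0.37) passed, and 0 did when adjusted over the list alone. Camera called neither list (Benjamini-Hochberg adjusted p = 0.698 for both). Of 4 erythroid genes, too few to test as a list, the erythropoietin receptor gene Epor rose by 1.73 (SE 0.06). Several single calls rested on individual samples, with adjusted p between 0.051 and 0.134 where they were lost (limma, Benjamini-Hochberg). Plac8 missed the threshold without KO replicate 1 or any WT sample (highest adjusted p 0.071). Hp and Vcan missed it without WT replicate 2 or 3 or KO replicate 1 or 2 (highest adjusted p 0.117 and 0.132). Cd209a missed it without WT replicate 2 or KO replicate 2 or 3 (0.058), and Btla without WT replicate 1 or 2 or KO replicate 1 (0.071). With gene values from exon-level probesets Zbtb46 changed by 0.81 and Btla by -0.44. Zbtb46 kept its call only without KO replicate 1, Mobp only without WT replicate 3 and Clu only without WT replicate 1 (highest adjusted p 0.134, 0.134 and 0.115). Vtn missed it without WT replicate 1 or 2 or KO replicate 1 or 3 (0.106). These 9 genes and Pecam1 also missed the threshold under at least 1 other processing, with Pecam1 at an adjusted p of 0.057 in the equal-variance test.

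Of 18 measured chromosomal neighbours of Nrros, 3 were higher and 2 lower. Pigz, of glycolipid anchor synthesis, rose by 1.72 (SE 0.08) and the phosphatidylcholine enzyme gene Pcyt1a by 0.57 (SE 0.10), or by 0.33 with gene values from exon-level probesets. Ncbp2 (-0.41) and Senp5 (-0.32) were lower. Both missed limma's threshold without each of 4 samples, WT replicates 2 and 3 and KO replicate 3 in both cases, KO replicate 2 for Ncbp2 and WT replicate 1 for Senp5 (highest Benjamini-Hochberg adjusted p 0.104 and 0.082). The median of this list was -0.033, its mean 0.073 and camera's direction upward (Benjamini-Hochberg adjusted p = 0.755). That median lay between -0.041 and -0.0037 with each sample left out and was 0.00049 without the dimmest clusters.

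In all, camera called 11 of 24 lists, 3 higher and 8 lower, and 2 with an estimated correlation, homeostatic microglia and border-associated macrophages. At the preset correlation the 9 other splits of the 6 samples gave 3 to 11 called lists, and the homeostatic and border-associated lists passed in all 9. Each of these splits mixes the groups unequally and so keeps part of the group difference. They therefore give no rate of calls without a difference. The count of called lists fell to 6 without WT replicate 2, to 7 without KO replicate 2 and to 6 without the dimmest clusters. For 18 of the 26 lists the number of members past the threshold was the same over all genes and adjusted over the list alone.

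**Figure D3:**
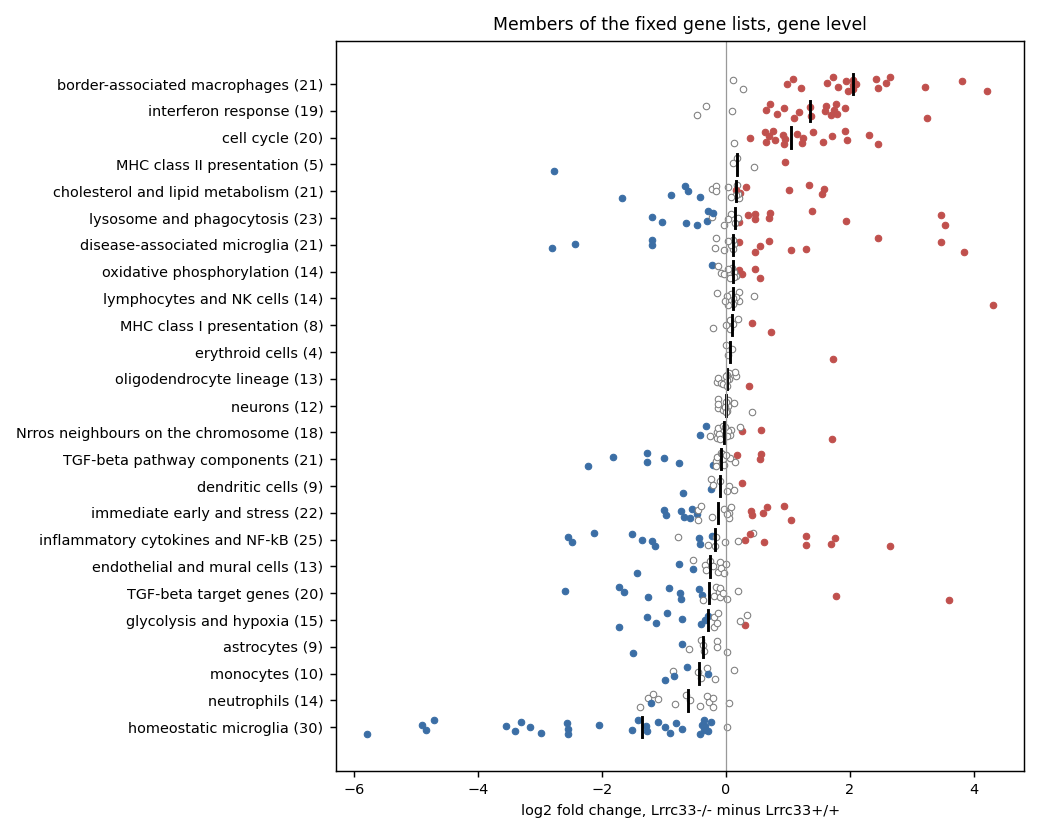
Log2 fold change (KO-labelled minus WT, horizontal axis) of each measured member of 25 gene lists, with the number of measured members in brackets. Filled points passed limma's threshold (red higher, blue lower), open points did not, and black bars are list medians. The homeostatic list lies furthest to the left (median -1.35) and the border-associated macrophage list furthest to the right (median 2.05).

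At the exon level 58662 of 1236087 probesets passed limma's test (4.75%), with 31961 higher and 26701 lower in the KO-labelled samples. Among probesets with 1 gene symbol 8.14% passed, and among the others 3.55%. The count was 30206 without WT replicate 1, 31768 without WT replicate 2, and 34139, 38717 and 35837 without KO replicates 1, 2 and 3. Without WT replicate 3 it was 41162. It was 99190 with trend and robust settings and 33603 with the replicate block.

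Probesets of the same gene often changed by different amounts. limma's diffSplice called 5278 of 16692 genes (31.6%) for differential exon usage, and 3432 without WT replicate 1. On simulated data with few changed genes it called 198 of 16492 genes without a single shifted probeset, 56.2% of its 352 calls there. That share depends on how many genes are changed, so it gives no false share for the 5278 genes. The smallest p belonged to Herc2, a large ubiquitin ligase gene, in which 76 of 115 probesets were lower, 0 were higher and 39 did not pass (limma diffSplice, Benjamini-Hochberg adjusted p = 4.1e-126). Its probeset changes ran from -2.78 to 0.09 around a gene-level change of -1.54. In Col27a1, a fibrillar collagen gene, 31 of 80 probesets were lower and 49 did not pass, with changes from -4.03 to 0.37. In Itsn1, an endocytic scaffold gene, 45 of 61 probesets were higher and 16 did not pass, with changes from -0.07 to 3.43. For each of these last 2 genes the adjusted p was 9.3e-112 (limma diffSplice, Benjamini-Hochberg). In none of these 3 genes did probesets pass in both directions. Genes with larger gene-level changes were called more often, from 20.8% of 8717 genes with a log2 change under 0.25 to 95.9% of 197 genes with a change of 2 or more. The median number of probesets per gene rose as well, from 10 to 16 between these bins, and was not held constant.

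**Figure D4:**
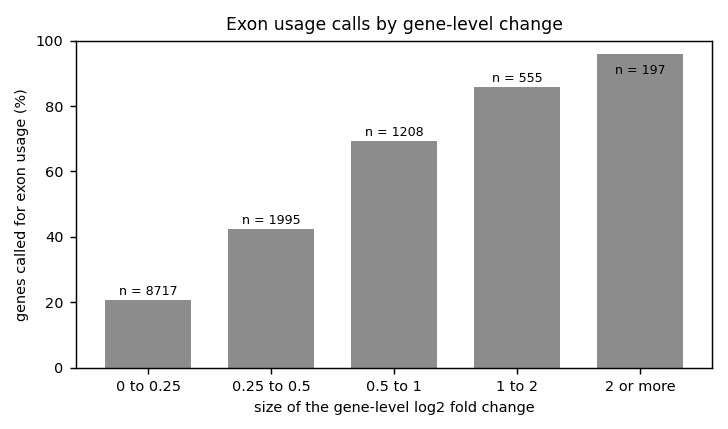
Percent of genes called for differential exon usage (vertical axis) by the size of the gene-level log2 fold change (horizontal axis), for 12672 genes measured at both levels, with the number of genes in each bar. The percent rises from 20.8 in the lowest bin to 95.9 in the highest, and the median number of probesets per gene from 10 to 16.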

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

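The fits of single genes, lists and Nrros probesets under these settings, and exon usage among genes with little gene-level change, were chosen after seeing the data. The count of changed clusters stayed within 1.5 times of 4758 under the alternatives that kept the same threshold, from 3786 without WT replicate 2 to 5046 with array weights, and was 856 with a 2-fold minimum. The homeostatic (median -1.51 to -1.29) and border-associated macrophage (2.02 to 2.11) lists kept direction and call throughout. The number of called lists was 6 without the dimmest clusters, 2 with an estimated correlation and 22 with fry's mixed test, which asks only whether members change in either direction, and 6 to 11 with each sample left out. The probeset count was 99190 with trend and robust settings and 30206 to 41162 with each sample left out. Exon usage calls numbered 3432 to 5333 with each sample left out and 1511 among genes with a gene-level change under 0.25, where fewer genes were tested. The Nrros difference was -0.053 with male signal as a covariate, which amounts to removing WT replicate 3, and -0.053 to 0.12 with each sample left out. Kdm5d was 0.040 with that covariate and -1.38 to 0.040 with each sample left out. Camera's direction turned for neurons and Nrros neighbours with gene values from exon-level probesets (medians -0.079 and -0.062), and with a sample left out for these lists and the oligodendrocyte list (medians -0.030 to 0.039 for neurons, -0.041 to -0.0037 for neighbours and -0.021 to 0.035 for oligodendrocytes), none of them called. Where fewer samples or genes do not explain a change, the cause was not tested. Of 98 named genes other than Nrros, 74 kept direction and side of the threshold throughout, and 1 (Kdm5d) turned. The filter on Nrros probesets bright in WT kept all 8 and so tested nothing. Equal replicate numbers showed no sign of pairing: deviations from group means correlated at -0.029, -0.0071 and 0.039 for numbers 1 to 3. Unequal numbers gave -0.031 to 0.041. A weak shared effect could go unseen, and the labels do not state a pairing. A fit with the replicate block called 4240 clusters, 11 lists, 33603 probesets and 4744 genes for exon usage. Signal over background limits the changes that can be seen in dim clusters.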

Other observations

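Families of genes put together after the data were seen were counted in the KO-labelled samples, and no test is given for them, since they hold genes already seen to change. Of 16 measured C-type lectin genes 9 were higher and 1 lower, among them Clec4a1 (2.89), Clec12a (2.43) and the mannose receptor gene Mrc1 (1.81), with Mrc2 lower (-1.19). Of 14 tight and adherens junction genes 6 were lower and 0 higher, led by Tjp1 (-4.92), Jam2 (-3.53) and F11r (-2.73). Of 20 macrophage transcription factor genes 5 were higher and 9 lower. Spic (4.80), the aryl hydrocarbon receptor gene Ahr (2.98) and Tfec (2.24) rose, while Sall1 (-5.79), Sall3 (-2.55), Bhlhe41 (-1.63) and the interferon regulatory factor genes Irf8 (-0.40) and Irf5 (-0.54) were lower. Spi1, which encodes the myeloid factor PU.1, did not pass (-0.14). Of 15 genes of Toll-like receptors and their partners 5 were higher and 5 lower, with Tlr8 at 3.65 and Tlr3 at -1.54.

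Further families held fewer or mixed changes. Of 18 integrin subunit genes 2 were higher and 6 lower, with Itgal at 1.51 and Itgb3 at -2.23. Of 19 semaphorin, plexin and neuropilin genes 8 were higher and 4 lower, with Plxnc1 at 2.79 and Sema4g at -3.03. Of 13 purine receptor and nucleotidase genes 4 were higher and 4 lower, with P2rx4 at 1.51 and Adora3 at -4.63, or -1.06 with gene values from exon-level probesets. Of 18 chemokine and chemoattractant receptor genes 5 were higher and 6 lower, with Ccr1 at 1.43 and Ccrl2 at -1.47. Of 18 extracellular protease genes 6 were higher and 3 lower, with Adam19 at 3.61 and Adamts1 at -3.60. Of 6 Fc receptor genes 3 were higher and 0 lower, with Fcgr4 at 1.12 and Fcgrt at 1.12. Rebuilding gene values from exon-level probesets added list members with no gene-level value, of which those given here were named after their values were seen. The border-associated list gained 5, all higher, among them Ms4a7 (3.54), the ceruloplasmin gene Cp (3.87) and Ifitm2 (3.44). The homeostatic list gained 3, all lower: Serpine2 (-4.91), Gal3st4 (-3.93) and Golm1 (-2.91). Other lists were mixed. The disease-associated list gained 8, of which 3 were higher and 3 lower. Lilrb4a (3.19), Lyz2 (2.15) and Cd63 (0.89) rose, while Cst7 (-1.76), Ccl6 (-1.27) and Itgax (-0.83) fell. MHC class II presentation gained 5, with 0 higher and 1 lower, H2-Ob (-1.50).

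Of the tests that follow, those on cell mixtures, on the Nrros signal and on strain variants near Nrros were chosen after the results were seen. The homeostatic microglia list was lower and the border-associated macrophage list higher in the KO-labelled samples. The tables argue against 10% or more unchanged microglia mixed with another cell type, since 5 of the 30 homeostatic genes (Sall1, Adgrg1, Sparc, Slc2a5 and Tmem119) had an upper 95% bound under 10% of their WT level. The monocyte genes measured did not rise as a list. The prediction of a rise was written after this list was seen to be lower, so its outcome was already known. It gives no verdict on blood monocytes in the gate or on cells derived from them. The median of the monocyte list was -0.43, and -0.59 to -0.34 with each sample left out, where a rise was predicted. Its bootstrap 95% interval, -0.83 to -0.28, resampled genes and so does not measure the spread between samples. Without the dimmest clusters 5 of the 10 genes were left, so a small share of such cells could go unseen. Lyz1, named after its values were seen, stood at 2.00. It was read only by exon-level probesets and is close in sequence to the macrophage gene Lyz2. Another brain macrophage type in place of microglia, or a change within microglia, cannot be told apart here: no sample of another type was measured, and Lyve1 stood at 0.12 while 19 of the 21 genes of that list rose. A change of cell state with the genotype stays a hypothesis.

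Nrros signal was not lower in the samples labelled KO. Loss of the whole transcript is argued against, since the Nrros probeset with the largest fall changed by -0.25. The lowest 95% bound over the 8 probesets was -0.83. It was taken without the degrees of freedom that limma adds, and so is wider than the bound of the fit itself. An exchange of 1 sample between the groups is argued against as well, since each sample correlated better with both samples of its own group than with any of the other, by at least 0.0289. Such an exchange would also not account for Nrros levels of 9.86, 9.89 and 9.83 (log2) in KO replicates 1 to 3. An exchange of the labels of whole groups would leave these correlations unchanged and was not tested. An allele that removes a part which the 8 named probesets do not read cannot be told apart from other reasons, since the positions of these probesets are not given in the sources used here. RNA that is made but yields no protein was not tested.

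Exon usage was called in 5278 genes. If compression near background or saturation were the cause, under 10% of genes with a gene-level change under 0.25 should have been called, and 20% or more if not. The observed 20.8% lay above 10%, but its exact 95% binomial interval, 19.97% to 21.7%, reaches just below 20%. That interval also treats genes of the same arrays as independent, and diffSplice's adjusted p was too small on simulated data. The prediction therefore does not decide whether compression was the cause. Compression stays open, also since the called share rose with the gene-level change. With probesets above the median in both groups 4340 genes were called. Probesets that read variants of another strain near Nrros may add calls, but the odds ratio within 10 Mb was 1.19 (Fisher's exact test, 95% interval 0.819 to 1.72), which does not decide it. No biological explanation was tested.

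The 10 possible splits of the 6 samples into 3 and 3 are too few for a share under 0.05. Each of the 9 other splits mixes WT and KO-labelled samples unequally. Its contrast keeps part of the group difference, and the rest widens the spread within its groups. Its counts are therefore no measure of what arises without a difference. The real split gave 4758 clusters and 58662 probesets, and the highest of the 9 others 0 and 0. For exon usage the real split gave 5278 genes and the highest other 20, so in each of these 3 counts 1 of 10 splits gave as many. For gene lists 2 of 10 splits gave as many, 11 in the real split and 11 in the highest other, which set WT replicates 1 and 2 and KO replicate 1 against the rest.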
